A study of Lactuca sativa with 28 samples.

How the data were processed

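Lettuce achenes were treated with 0.1 µM KAR1, 10 µM InhA or both and compared with water controls of the same time on custom Agilent 2-colour arrays, 28 in all in 7 groups of 4. Per the labels' protocols, 50 achenes were germinated per harvest at 2 and 10 h, at least 20 germinated achenes with a radicle of 1 mm were taken at 24 h, each harvest was made in 3 biological replicates, total RNA with an integrity number of at least 8 was used, and RNA was amplified and labelled with Cy3 or Cy5. Groups, times and the dye of each RNA were taken from the labels of each channel.

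The deposited scanner tables hold spot intensity on a linear scale. For the 16 arrays of 10 and 24 h, full tables were written by Feature Extraction 9.5.1.1, per the file headers, with mean and median foreground, median background and quality flags. For the 12 arrays of 2 h the deposited tables are reduced to median foreground and median background intensity, with no flags. Agilent's own log ratio, in log10 of Cy5 over Cy3, is deposited for the full tables only. The authors also deposited a value table of log2 ratios for all arrays. Set against the scanner values, it holds log2 of Cy5 over Cy3 with array medians between -0.03 and 0.01, correlating at r = 0.80 to 0.98 with the ratios computed here (slope 0.87 to 1.47). How the authors corrected background and normalized it is not given in the sources used here; the submitters' processing notes name limma. Flag columns, coded 0 or 1 per the file headers, were used as deposited.

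From the scanner tables, background was corrected with normexp (offset 50) on mean foreground and median background, or on median foreground for the reduced tables. Each array was normalized by loess, with the 1264 positive and 153 negative control spots at weight 0 and then left out, and spots flagged as non-uniform were left out. Each log ratio was turned so that treated over water is positive, and the repeat spots of a probe were averaged (13668 probes have 1 spot, 14852 have 2 and 20 have more). Probes were 50 to 60 bases long. A probe was tested if it was well above background in either channel on at least 50% of the arrays of a group, by the scanner's flags or, for the reduced tables, by the 95th percentile of the negative controls. This left 28118 of 28540 probes, so the filter removed only 422. Named probes were above background in both channels on every array of the group they were named in. For a contrast only the group named first was checked. The 24 h InhA arrays were thus not checked for probes 129274, 127512 and 152861. The ratio of the variance between 2 arrays to the variance between repeat spots, over the probes in 2 spots, was used to ask whether same-dye arrays of a group vary like separate RNA. For opposite-dye pairs the difference also holds the probe-specific dye effect, which was not taken out. The ratio was first computed with the noise of repeat spots within each array, which gave 0.40 to 1.82 for same-dye and 2.21 to 5.55 for opposite-dye pairs. Since deviations between repeat spots recur from array to array, that noise is too large, and after these values had been seen it was replaced by the noise of repeat spots in the difference of the 2 arrays, which is the version reported; a version on the brightest 25% of probes was added then too. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.06.

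All 28 arrays entered 1 fit in limma 3.58.1 (R 4.3.3, lmFit and eBayes) with a term for each group and a probe-specific dye term, and the compounds and the mixture were compared by contrasts of that fit. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over the probes tested. These choices, the first set of alternatives below and the rule for naming probes were fixed before the data were examined. With no gene names, that rule takes, per comparison, the 2 largest rises and the 2 largest falls among called probes with the same sign on all 4 arrays. It did not cover 2 points, which were set afterwards: for a contrast, all arrays of a group had to lie on the same side of all arrays of the other, and a probe sharing 25 bases with one already taken was skipped. The files describe every probe as unknown, and 0 probe identifiers matched the table of lettuce genes given for this work (assembly Lsat_Salinas_v11), so the gene lists fixed beforehand, for hormone, cell wall, storage and stress genes among others, could not be used and no gene is named. The fit was tested on simulated data for KAR1 against water at 10 h: of 200 changed probes among 28118, it recovered 88.1% of those changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 9 false calls. For KAR1 minus InhA at 10 h it recovered 59.7%, 98.5% and 100%, with 7 false calls. The simulated arrays were independent and had 1 dye effect common to all groups. These rates therefore need not hold if same-dye arrays share RNA or if dye effects differ between groups.

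The first set of alternatives was no background correction, Aquantile after loess, Agilent's log ratio, the authors' values, no filter, only the arrays compared without a dye term, a replicate block, and each array left out in turn. Added after seeing the data were a dye term for each group, median centring in place of loess, and same-dye arrays averaged before the fit. A slide block was not fitted, because slide and group could not be told apart. Each group was taken to have a slide of its own, although the headers of the 24 h InhA arrays carry the slide number of the mixture's arrays. Shared controls were simulated in 20 draws from the fitted spread, with controls common to both groups. For levels of the water channel alone, channels were taken after loess and Aquantile. Figures were drawn with matplotlib 3.10.9.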

Results

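Gene expression was measured on 2-colour oligonucleotide arrays in achenes (the dry, seed-bearing fruits) of lettuce, Lactuca sativa cultivar Grand Rapids. Achenes were imbibed in water or in solutions of butenolides found in plant smoke. KAR1 (karrikin 1) at 0.1 µM is a germination stimulant, and InhA is a code-named butenolide that was applied at 10 µM as an inhibitor. Each of the 28 arrays carried RNA of treated achenes in 1 channel and RNA of achenes held in water for the same time in the other. The arrays fell into 7 groups of 4: KAR1 at 2, 10 and 24 h, InhA at 2, 10 and 24 h, and KAR1 plus InhA together at 2 h. The treated RNA carried Cy5 on 2 arrays of each group and Cy3 on the other 2. Early times were set around the response to KAR1, which can no longer be washed out after 2 h and is no longer blocked by InhA after 9 h. At 24 h the RNA of germinated and non-germinated achenes was combined in equal amounts, so those ratios do not reflect how many achenes had germinated.

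The array holds 28540 probes with numeric identifiers, and the files do not pair them with genes, so results are given by probe and probe sequence, with no genome position. After a filter on dim probes, 28118 probes were tested. Median foreground intensity ranged from 138 to 214 in Cy3 and from 80 to 190 in Cy5 on the 2 h arrays, from 75 to 119 and 77 to 134 at 10 h, and from 71 to 106 and 58 to 111 at 24 h. In the 24 h InhA group 36% to 53.9% of spots lay well above background in a channel, against 66.3% to 76.2% in the 24 h KAR1 group. Labels gave 3 biological replicates per harvest for 4 arrays and did not say which arrays share RNA. Arrays of 1 group with the same dye orientation differed by 1.03 to 2.40 times the variance between repeat spots (14 pairs), against 1.67 to 6.28 times for arrays of opposite orientation (28 pairs). On the brightest 25% of probes these ranges were 0.99 to 1.68 and 1.54 to 15.4. Differences between opposite orientations also hold probe-specific dye effects, so they do not show how far separate RNA would differ. The labels and the same-dye ratios leave open that the spread between arrays is technical, so p-values may be too small. Counts with same-dye arrays averaged to 1 value are given beside the main counts. Treated-over-water ratios of opposite orientation correlated across probes at r = 0.72 to 0.84 within the 24 h groups and at 0.13 to 0.66 at 10 h. At 2 h that correlation was -0.47 to 0.09, and across probes the dye component of the 3 groups had an SD of 0.127 to 0.196 on the log2 scale, against 0.109 to 0.141 for the treatment effects. That component, the mean Cy5 over Cy3 ratio of both orientations, also holds any difference between the RNA on them. Correlations here and below are across probes, which are not independent replicates.

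The first comparison asked what KAR1 changed against water before its action became irreversible, at 2 h. In KAR1-treated achenes 305 probes were higher and 651 lower than in water. Probe 145507 (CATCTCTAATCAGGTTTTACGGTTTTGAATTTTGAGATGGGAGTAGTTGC) fell 6.82-fold, with a mean log2 ratio of -2.77 ± 0.40 (SD, n = 4 arrays; SE of the fit 0.15, adjusted p = 4.48e-11). Probe 126283 (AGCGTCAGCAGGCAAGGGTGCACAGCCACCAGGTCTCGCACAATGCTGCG) fell 4.98-fold, with a log2 ratio of -2.31 ± 0.21 (SD, n = 4; adjusted p = 4.48e-11). The largest rises were smaller: probe 146112 reached a log2 ratio of 0.75 ± 0.44 (SD, n = 4; adjusted p = 5.6e-05) and probe 132449 (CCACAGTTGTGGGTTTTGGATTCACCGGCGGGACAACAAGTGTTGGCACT) 0.69 ± 0.07 (SD, n = 4; adjusted p = 4.97e-05). No rise among the called probes reached 2-fold and 13 falls did; at an unadjusted p under 0.05, 4559 probes passed. Averaging same-dye arrays left 12 probes (1 higher, 11 lower), and with median centring in place of loess 22 did (1 higher, 21 lower). The rises of probes 146112 and 132449 passed in neither of these, and leaving out replicate 1, 3 or 4 lowered the count to 563, 615 and 542.

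At 10 h, when KAR1-treated achenes are past the stage at which InhA can block them, 1642 probes were higher and 2346 lower than in water. Probe 152207 (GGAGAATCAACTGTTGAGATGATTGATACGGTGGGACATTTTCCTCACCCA) rose 4.90-fold, with a log2 ratio of 2.29 ± 0.21 (SD, n = 4; SE 0.07, adjusted p = 9.16e-17). Probe 151989 (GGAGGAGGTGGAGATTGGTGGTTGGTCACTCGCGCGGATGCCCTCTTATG) rose 3.72-fold (log2 ratio 1.89 ± 0.08, SD, n = 4; adjusted p = 7.2e-07). Probe 144858 (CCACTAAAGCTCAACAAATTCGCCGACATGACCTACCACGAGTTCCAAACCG), which shares a stretch of at least 25 bases with 2 other probes, fell 3.86-fold (log2 ratio -1.95 ± 0.38, SD, n = 4; adjusted p = 1.04e-10). Probe 148044 (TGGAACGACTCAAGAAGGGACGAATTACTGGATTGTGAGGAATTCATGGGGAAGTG) fell 3.48-fold, from a narrow range of arrays (log2 ratio -1.80 ± 0.03, SD, n = 4; adjusted p = 1.01e-15). Of the 3988 changed probes, 3931 moved the same way on all 4 arrays and 38 changed at least 2-fold. Averaging same-dye arrays left 970 probes (401 higher, 569 lower), and with median centring 767 were higher and 5324 lower. Median centring also moved the log2 ratio of probe 151989 to 1.20, that of 144858 to -2.57 and that of 148044 to -2.52. The authors' deposited values gave 1738 higher and 1725 lower, and leaving out replicate 3 or 4 gave 2507 or 2383 changed probes.

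At 24 h KAR1 changed 6403 probes against water, 3430 up and 2973 down, of which 183 rose and 259 fell at least 2-fold. Probe 129274 (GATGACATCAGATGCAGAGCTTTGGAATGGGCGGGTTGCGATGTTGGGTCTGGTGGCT) rose 14.7-fold, with a log2 ratio of 3.88 ± 0.08 (SD, n = 4; SE 0.31, adjusted p = 4.26e-10). Probe 112386 (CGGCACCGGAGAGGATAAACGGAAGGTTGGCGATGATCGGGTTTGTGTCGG) rose 7.95-fold (log2 ratio 2.99 ± 0.14, SD, n = 4; adjusted p = 8.61e-16). Probe 115315 (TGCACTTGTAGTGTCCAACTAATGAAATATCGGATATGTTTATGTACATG), which shares at least 25 bases with 1 other probe, fell 11.1-fold (log2 ratio -3.47 ± 0.31, SD, n = 4; adjusted p = 4.08e-15) and probe 147314 (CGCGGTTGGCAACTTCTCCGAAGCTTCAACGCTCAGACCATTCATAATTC) by a similar amount (log2 ratio -3.46 ± 0.28, SD, n = 4; adjusted p = 6.22e-15). Probe 152207, which led the rises at 10 h, was still higher at 24 h (log2 ratio 2.79, SE 0.07, adjusted p = 3.44e-19). The averaged same-dye arrays gave 3260 changed probes, 1769 up and 1491 down, and the authors' deposited values gave 9674. More probes fell than rose in the authors' values (4768 up, 4906 down) and in Agilent's log ratio (3803 and 4094). Median centring gave 1225, 699 up and 526 down.

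**Figure D1:**
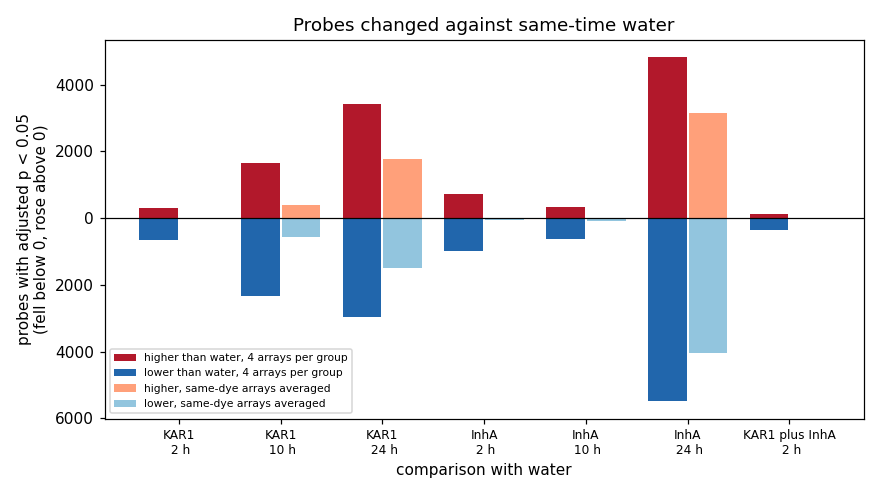
Number of probes that differed from same-time water (limma, adjusted p under 0.05) in each comparison, with rises above 0 and falls below 0 on the vertical axis; dark bars use 4 arrays per group and light bars 1 average per dye orientation. The 24 h comparisons hold the most probes in either form, 10327 for InhA and 6403 for KAR1 with 4 arrays per group.

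InhA was compared with water at the same times. At 2 h 717 probes were higher and 984 lower. The probes that led the falls under KAR1 also led them here: probe 145507 fell 4.74-fold (log2 ratio -2.24 ± 0.26, SD, n = 4; adjusted p = 2.02e-09) and probe 126283 3.83-fold (log2 ratio -1.94 ± 0.30, SD, n = 4; adjusted p = 9.2e-10). Probe 132449 rose as it did under KAR1 (log2 ratio 0.79 ± 0.23, SD, n = 4; adjusted p = 3.69e-06), and probe 122922 (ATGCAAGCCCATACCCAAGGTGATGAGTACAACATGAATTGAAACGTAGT) reached 0.67 ± 0.40 (SD, n = 4; adjusted p = 0.000355). Falls of at least 2-fold numbered 28. The count moved with the processing: 78 probes passed with same-dye arrays averaged (11 higher, 67 lower), 17 with these 4 arrays alone and no dye term, and 5376 with a dye term for each group. The rises of probes 132449 and 122922 did not pass with median centring or with the 4 arrays alone, nor that of 122922 with same-dye arrays averaged. Higher and lower calls split 323 to 791 without background correction, 222 to 638 in the authors' values and 5 to 62 with median centring, and the total was 528, 4352 and 641 without replicates 1, 2 and 3.

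At 10 h InhA changed 328 probes up and 633 down. That total is below the one at 2 h, but the order turned with same-dye arrays averaged (78 at 2 h, 104 at 10 h), with the compared arrays alone (17 and 1386) and without background correction (1114 and 1326). Probe 147348 (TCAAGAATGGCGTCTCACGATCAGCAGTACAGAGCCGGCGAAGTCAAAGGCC) rose 2.70-fold (log2 ratio 1.43 ± 0.13, SD, n = 4; adjusted p = 7.97e-09) and probe 000047 (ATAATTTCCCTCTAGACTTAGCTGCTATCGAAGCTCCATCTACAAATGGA) 2.27-fold (log2 ratio 1.18 ± 0.07, SD, n = 4; adjusted p = 9.23e-09). Both were also higher under KAR1 at 10 h, by log2 ratios of 1.88 (adjusted p = 4.41e-11) and 1.41 (adjusted p = 2.28e-10). Probe 145942 (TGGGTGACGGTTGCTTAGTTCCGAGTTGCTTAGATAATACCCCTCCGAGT) fell 5.23-fold (log2 ratio -2.39 ± 0.24, SD, n = 4; adjusted p = 6.57e-13), whereas under KAR1 its log2 ratio was -0.17 (adjusted p = 0.394). Probe 128890 (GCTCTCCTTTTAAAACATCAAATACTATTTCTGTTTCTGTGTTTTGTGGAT) fell 2.91-fold (log2 ratio -1.54 ± 0.17, SD, n = 4; adjusted p = 6.37e-10). With same-dye arrays averaged 104 probes passed (17 higher, 87 lower), and with median centring 54 did (2 higher, 52 lower). In Agilent's log ratio probe 128890 had a log2 value of -2.41. Leaving out replicate 1, 2 or 3 gave 488, 634 and 617 changed probes.

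At 24 h InhA left 4835 probes higher and 5492 lower than in water, 473 and 1033 of them at least 2-fold. This was the largest count against water, except with median centring, where KAR1 at 10 h had 6091 and InhA at 24 h 4178. Probe 146293 (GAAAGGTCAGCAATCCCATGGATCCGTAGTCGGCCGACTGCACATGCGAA) fell 31.3-fold, with a log2 ratio of -4.97 ± 0.28 (SD, n = 4; SE 0.09, adjusted p = 9.74e-23). Probe 147570 (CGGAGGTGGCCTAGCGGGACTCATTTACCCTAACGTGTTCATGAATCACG), which shares at least 25 bases with 1 other probe, fell 20.7-fold (log2 ratio -4.37 ± 0.14, SD, n = 4; adjusted p = 5.5e-24). Probe 119383 (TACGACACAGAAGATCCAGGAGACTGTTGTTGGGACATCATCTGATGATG) rose 6.72-fold (log2 ratio 2.75 ± 0.45, SD, n = 4; adjusted p = 1.57e-15) and probe 112681 (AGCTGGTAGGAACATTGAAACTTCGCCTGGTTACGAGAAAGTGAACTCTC) 6.26-fold (log2 ratio 2.65 ± 0.72, SD, n = 4; adjusted p = 1.57e-15). Both of these were lower under KAR1 at 24 h, by log2 ratios of -2.0 (adjusted p = 2.18e-12) and -3.32 (adjusted p = 8.8e-17). On averaged same-dye arrays 7191 probes passed, 3151 up and 4040 down. Median centring gave 772 up and 3406 down. The balance turned in the authors' values (5773 up, 4724 down) and in Agilent's log ratio (6674 and 6172), which put probe 146293 at -5.58.

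**Figure D2:**
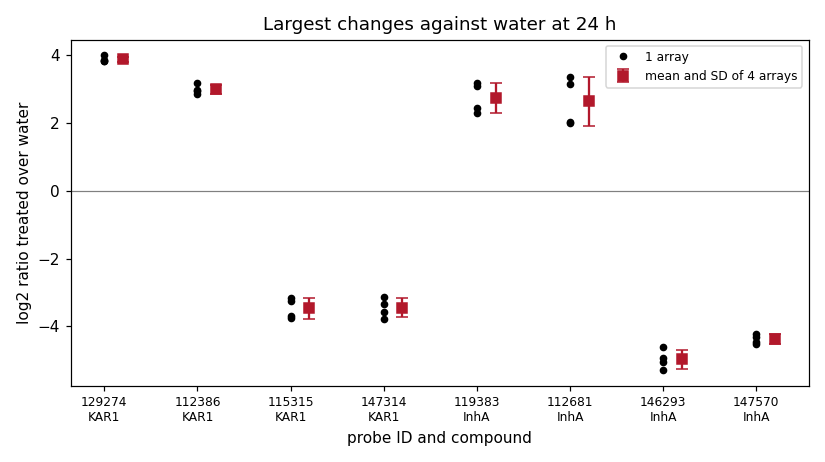
Log2 ratio of treated over water at 24 h for the 2 probes with the largest rise and the 2 with the largest fall under each compound, with black points for single arrays and red squares for the mean and SD of 4 arrays. For each probe all 4 arrays lie on the same side of 0, which the rule for naming probes required. Means run from -4.97 for probe 146293 under InhA to 3.88 for probe 129274 under KAR1.

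KAR1 and InhA were then set against each other at matched times; their doses differed, 0.1 µM against 10 µM. At 24 h their ratios to water differed for 10796 probes, 5937 higher under KAR1 and 4859 higher under InhA, and 2825 differed at least 2-fold. The water channels of the 2 slides differed from each other by an SD of 0.60 on the log2 scale at 24 h (0.08 at 10 h), against 0.29 for the KAR1 and 0.48 for the InhA effects, and each compound had a slide of its own. As labelled, probe 129274 differed most in favour of KAR1, by 5.51 on the log2 scale (95% interval 4.61 to 6.40, adjusted p = 1.24e-10), with 3.88 ± 0.08 under KAR1 and -1.63 ± 1.95 under InhA (SD, n = 4 each). The interval and p-value rest on 1 spread per probe for all groups, so with an SD this large under InhA they may be too small. Probe 127512 (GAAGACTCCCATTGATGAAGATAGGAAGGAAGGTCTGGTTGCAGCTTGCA) followed with a difference of 5.47 (interval 4.89 to 6.04, adjusted p = 3.64e-14), which was 6.79 in Agilent's log ratio and 6.05 in the authors' values. Probe 112681 was lower under KAR1 than under InhA by a log2 difference of -5.97 (interval -6.30 to -5.63, adjusted p = 2.34e-19) and probe 152861 (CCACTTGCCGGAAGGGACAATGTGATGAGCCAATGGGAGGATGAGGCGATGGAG) by -5.94 (interval -6.23 to -5.65, adjusted p = 2.2e-20). The log2 ratios of probe 127512 were 1.20 ± 0.23 under KAR1 and -4.27 ± 1.035 under InhA (SD, n = 4 each), so its interval may be too narrow as well. Probes 129274, 127512 and 152861 were not checked for signal above background on the InhA arrays. Of the 4613 probes that changed under both compounds, 2099 rose under KAR1 and fell under InhA and 2059 did the reverse, so 90.1% moved in opposite directions. The first of these sets had median log2 ratios of 0.36 under KAR1 and -0.56 under InhA, and the second -0.40 and 0.58. Only 178 rose under both, against 589.5 from independent lists of these sizes, and 277 fell under both, against 580.3. Across probes, which are not independent replicates, the fold changes correlated at r = -0.55. Dyes and treatments are stated for each channel in the labels, so the directions were kept as labelled. A test of the channels could not exclude an exchange of treated and water labels on either slide. An exchange on the InhA slide would turn the r of 0.45 between InhA at 10 h and at 24 h, where 698 of 777 shared calls went the same way. It would also turn the r of -0.169 between KAR1 at 10 h and InhA at 24 h. An exchange on the KAR1 slide would turn the sign of each KAR1 ratio at 24 h: the 90.1% would then have moved the same way, at r = 0.55. The differences would become -2.25 for probe 129274, 3.07 for 127512, 0.67 for 112681 and 0.93 for 152861. An exchange on the InhA slide instead would give 2.25, -3.07, -0.67 and -0.93. Averages of same-dye arrays differed for 7794 probes, and with median centring 3546 were higher and 1196 lower under KAR1. The authors' values turned the balance, to 6116 higher and 6618 lower, and Agilent's log ratio gave 6752 and 6693.

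**Figure D3:**
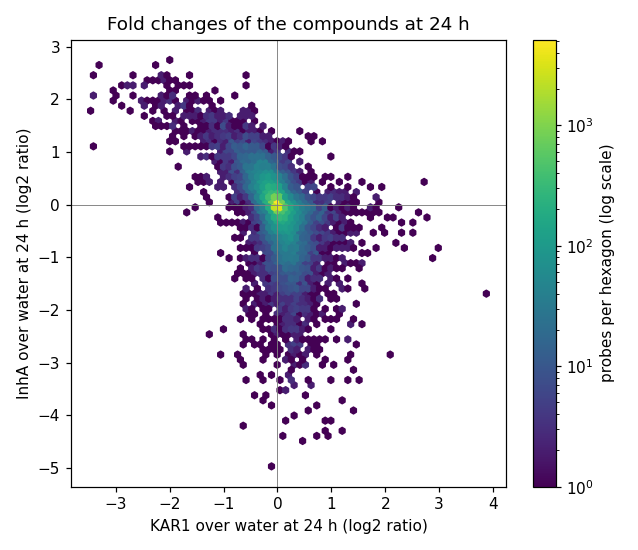
Fold change against water at 24 h for each tested probe, with the KAR1 log2 ratio on the horizontal axis and the InhA log2 ratio on the vertical axis; colour gives the number of probes per hexagon on a log scale. Probes that fell under KAR1 lie mostly above 0 for InhA, and the correlation across probes is -0.55.

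At 10 h the compounds differed for 971 probes, 502 higher and 469 lower under KAR1. Probe 145942 was higher under KAR1 by 2.22 on the log2 scale (95% interval 1.91 to 2.52, adjusted p = 1.54e-09) and probe 152207 by 2.08 (interval 1.88 to 2.29, adjusted p = 3.7e-12). Probe 145507 was lower under KAR1 by a log2 difference of -1.70 (interval -2.15 to -1.25, adjusted p = 3.13e-05), and probe 127050 (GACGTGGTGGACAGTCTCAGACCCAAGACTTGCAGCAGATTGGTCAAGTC) by -1.49 (interval -2.33 to -0.64, adjusted p = 0.0419). In contrast to 24 h, fold changes of the compounds correlated positively at 10 h, with r = 0.43 across probes and 0.87 with median centring. Simulated unchanged groups with wholly shared controls gave r = 0.50, which that setting fixes. They gave 0 probes called in both, which the lack of any effect fixes. Of 585 probes changed by both, 156 rose and 358 fell under both, against 19.2 and 52.8 from independent lists. For 99.2% of probes the 95% interval of the difference lay within 2-fold either way. When same-dye arrays were averaged, 43 probes differed (34 higher, 9 lower under KAR1), without probes 145507 and 127050; with median centring only probe 145507 did, which was lower. More probes were lower than higher under KAR1 with the compared arrays alone (1236 higher, 1585 lower) and with a dye term for each group (1224 and 1528). Without KAR1 replicate 3 or 4 the count was 582 or 540, and the difference of probe 127050 did not pass whichever of the 8 arrays was left out (log2 differences -1.60 to -1.37).

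At 2 h the compounds differed for 370 probes, 195 higher and 175 lower under KAR1. Probe 149770 (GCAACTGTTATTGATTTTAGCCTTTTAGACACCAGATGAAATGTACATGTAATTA) was higher under KAR1 by 1.39 on the log2 scale (95% interval 0.95 to 1.84, adjusted p = 0.00196) and probe 112805 by 1.35 (interval 0.87 to 1.83, adjusted p = 0.00401). Probe 143714 (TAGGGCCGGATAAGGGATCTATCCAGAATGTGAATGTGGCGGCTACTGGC) was lower under KAR1 by a log2 difference of -0.87 (interval -1.09 to -0.65, adjusted p = 7.04e-05) and probe 146213 by -0.64 (interval -0.92 to -0.36, adjusted p = 0.0174). Under InhA probe 149770 had an SD of 0.71 and probe 112805 one of 0.60 (n = 4 arrays), against 0.05 and 0.19 under KAR1. Their intervals rest on 1 spread per probe for all groups and may be too narrow. For 99.5% of probes the interval of the difference lay within 2-fold either way. None of these 4 differences passed with same-dye arrays averaged, where 2 probes did, both higher under KAR1, and none passed with median centring, where 910 had an unadjusted p under 0.05. Higher and lower calls split 164 to 58 without background correction and 151 to 71 in the authors' values, but 1488 to 1846 with a dye term for each group and 325 to 359 with the replicate block. The difference of probe 146213 did not pass without KAR1 replicate 2 or 4 or InhA replicate 1 or 3 (log2 differences -0.57, -0.55, -0.56 and -0.60). The count was 199 without KAR1 replicate 1, and 119, 1991 and 93 without InhA replicates 1, 2 and 3.

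The mixture was included to see how far the responses to the compounds diverge when both are present. At 2 h KAR1 plus InhA changed 475 probes against water, 122 up and 353 down. Probe 152855 (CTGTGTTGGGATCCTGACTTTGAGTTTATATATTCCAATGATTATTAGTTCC) fell 2.47-fold (log2 ratio -1.31 ± 0.46, SD, n = 4; adjusted p = 1.4e-06) and probe 112805 (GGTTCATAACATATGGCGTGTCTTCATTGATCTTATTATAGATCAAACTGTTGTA), which shares at least 25 bases with 1 other probe, 2.40-fold (log2 ratio -1.26 ± 0.32, SD, n = 4; adjusted p = 6.49e-05). Both fell under InhA alone as well (log2 ratios -1.04, adjusted p = 2.01e-05, and -1.13, adjusted p = 0.000113), while under KAR1 alone their log2 ratios were 0.24 (adjusted p = 0.389) and 0.22 (adjusted p = 0.571). Probe 146975 (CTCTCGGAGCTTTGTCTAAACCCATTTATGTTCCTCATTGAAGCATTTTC) rose by 0.96 ± 0.47 (log2, SD, n = 4; adjusted p = 1.83e-06) and probe 132449 by 0.67 ± 0.35 (log2, SD, n = 4; adjusted p = 6.46e-05). Of these 4 probes none passed with same-dye arrays averaged, with median centring or with the 4 arrays of the mixture alone. Averaging gave 15 other probes (2 up, 13 down), median centring also 15, all down, and the 4 arrays alone 1. Without background correction the log2 ratio of probe 132449 was 1.13. A dye term for each group gave 1786 and no background correction 1733, and the count was 1121, 185 and 160 without replicates 2, 3 and 4.

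Against InhA alone the mixture differed for 10 probes, 7 higher and 3 lower; 1602 had an unadjusted p under 0.05. Probe 145507 was higher in the mixture by 1.68 on the log2 scale (95% interval 1.23 to 2.12, adjusted p = 0.000922) and probe 126283 by 1.34 (interval 0.98 to 1.71, adjusted p = 0.000922). Probe 153075 (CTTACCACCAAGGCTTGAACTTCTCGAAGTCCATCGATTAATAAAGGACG) was lower by a log2 difference of -0.87 (interval -1.07 to -0.66, adjusted p = 0.000202) and probe 119554 (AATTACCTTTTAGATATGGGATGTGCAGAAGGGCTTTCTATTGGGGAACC) by -0.56 (interval -0.76 to -0.36, adjusted p = 0.0241). Against KAR1 alone the mixture differed for 176 probes, 74 higher and 102 lower. Probe 145507 was higher there too, by 2.20 (interval 1.76 to 2.65, adjusted p = 1.64e-06), as was probe 148076 (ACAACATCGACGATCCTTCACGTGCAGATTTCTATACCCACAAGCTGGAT), by 1.84 (interval 1.05 to 2.64, adjusted p = 0.0204). Probes 152855 and 112805 were lower in the mixture than under KAR1, by log2 differences of -1.54 (adjusted p = 3.95e-05) and -1.48 (adjusted p = 0.00138). Probe 145507 thus fell under each compound alone, and had a log2 ratio of -0.57 in the mixture (adjusted p = 0.059). Without InhA replicates 1, 2 and 3 the count against InhA was 5, 21 and 5, and without mixture replicates 1 and 4 it was 5 and 6. Against KAR1 it was 111 without KAR1 replicate 1, and 440, 98 and 77 without mixture replicates 2, 3 and 4. For 99.8% of probes the 95% interval of the difference from InhA lay within 2-fold either way. The median interval was 0.17 wide to each side on the log2 scale, so smaller differences may have been missed. The small count against InhA thus does not show that the mixture and InhA acted alike. The difference of probe 148076 did not pass without KAR1 replicate 2 or 4 or mixture replicate 1, 3 or 4 (log2 differences 1.73, 1.75, 1.82, 1.79 and 1.94). That of probe 119554 did not pass without InhA replicate 2, 3 or 4 or mixture replicate 3 or 4 (-0.50, -0.56, -0.57, -0.50 and -0.49). After same-dye arrays were averaged, the mixture differed from InhA for 0 probes in limma (509 at an unadjusted p under 0.05) and from KAR1 for 2, both lower, none of the probes named here among them. Splits of higher to lower calls moved to 7 to 30 against InhA without background correction, and against KAR1 to 125 to 290 without background correction and 35 to 87 in the authors' values. A dye term for each group gave 66 to 67 against InhA and 758 to 596 against KAR1. Against KAR1 median centring left only probe 145507, which was higher, and against InhA it left 0 (378 at an unadjusted p under 0.05).

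Comparisons of the same time may have used the same water RNA, so correlations were set against simulated unchanged groups with wholly shared controls, which gave r = 0.50 and a covariance of 0.00289. Those groups held no effect, so their r is set by the shared controls and a shared call is hardly possible. Their 0 shared calls therefore do not show what shared controls add where groups hold effects. The mixture and InhA at 2 h correlated at r = 0.64 with a covariance of 0.00987, and 73 probes rose and 261 fell in both, against 3.1 and 12.4 from independent lists. Taking the groups from arrays of different replicate number gave r = 0.36 and 0.52, with a mean covariance of 0.00875. Such splits hold fewer arrays per group, which by itself lowers r. The mixture and KAR1 correlated at r = 0.23 with a covariance of 0.00286, no larger than the simulated one. In both, 17 probes rose and 70 fell, against 1.3 and 8.2 from independent lists. This order of the correlations turned with median centring, which gave r = 0.24 for the mixture with InhA and 0.65 with KAR1. KAR1 and InhA at 2 h had r = 0.25 and a covariance of 0.00413, with r = 0.10 and 0.21 between arrays of different number, and at 10 h r = 0.43 and a covariance of 0.00855, with r = 0.40 and 0.41 between arrays of different number. At 24 h the covariance was -0.0761. Between times, InhA at 10 h and InhA at 24 h correlated at r = 0.45, with 232 probes up and 466 down at both times against 56.4 and 123.7 from independent lists. KAR1 at 10 h and KAR1 at 24 h correlated at r = 0.07, with 392 up and 541 down at both against 200.3 and 248.0. Another 780 moved in opposite directions: 253 rose at 10 h and fell at 24 h and 527 did the reverse, against 173.6 and 286.2. Overlap was thus raised in each direction. KAR1 at 24 h ran against InhA at 10 h (r = -0.38). An exchange of labels on the 24 h KAR1 slide would turn the signs of these correlations with KAR1 at 24 h. Times were taken to be on separate slides, although the headers of the 24 h InhA arrays carry the slide number of the 2 h mixture arrays. The 2 h files were also deposited in a reduced form, so time and slide cannot be told apart.

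**Figure D4:**
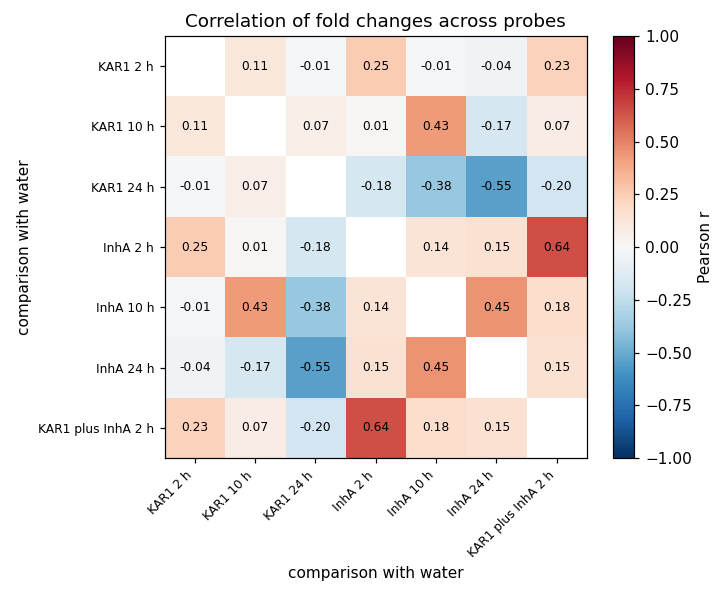
Pearson correlation, across tested probes, of the log2 fold changes against water for each pair of comparisons, with the 7 comparisons on both axes and colour and number giving r. InhA and the mixture at 2 h stand at 0.64 and KAR1 and InhA at 24 h at -0.55.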

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

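The test of the mixture against InhA at 10 h, the test of the dye component and the test of exchanged labels on the InhA slide alone were chosen after their results had been seen; the other tests below were set down before, and ranges over arrays or pairs were added afterwards.

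Effects against water differed between treatments for 10796 probes (KAR1 minus InhA at 24 h), 971 (at 10 h), 370 (at 2 h), 176 (mixture minus KAR1) and 10 (mixture minus InhA). Of the 35 splits of the 8 arrays into 4 and 4, only the real split, 1 of 35, gave as many calls at 24 h (highest other 1968) and for the mixture minus KAR1 (highest other 161). Chance can be excluded there only if the 8 arrays are separate samples; if same-dye arrays share RNA, the splits are too few, and with those arrays averaged the mixture minus KAR1 had 2 calls. For KAR1 minus InhA it cannot be excluded at 10 h (2 of 35 splits, highest other 1193) or 2 h (3 of 35, highest other 6464), nor for the mixture minus InhA (6 of 35, highest other 6094). In each of these the highest other split was the one that separates the dye orientations. So it was for the mixture minus KAR1, where that split gave 161 calls against 176 and the next highest 134. This points to a structure of the arrays by dye. At 10 h no further split called a probe. Against water, the 8 patterns of sign of 4 arrays are too few for a share under 0.05. The real counts and the highest others were 956 and 511 (KAR1 at 2 h), 3988 and 0 (10 h), 6403 and 59 (24 h), 1701 and 3910 (InhA at 2 h), 961 and 2 (10 h), 10327 and 3798 (24 h) and 475 and 415 (mixture). As many calls came from 1 of the 8 patterns, the real one, in each comparison except InhA at 2 h, where they came from 3 of 8 and the pattern that follows the dyes gave 3910.

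Weak hybridisation of the InhA slide as the source of the opposite fold changes of KAR1 and InhA at 24 h is argued against by the 9176 probes well above background in both channels of all 8 arrays, over which r was -0.592. Loess normalization is argued against by r = -0.527 with median centring in its place. An exchange of treated and water labels on 1 of the slides stays open: on the KAR1 slide the channels labelled treated were 1.04 times as far from the water of the InhA slide as those labelled water (mean squared log2 distance, 0.90 to 1.13 over its arrays), and the bounds set for a decision were 0.9 and 1.1. On the InhA slide the ratio was 1.284, which goes against an exchange there, but with 1.09 to 1.52 over its arrays it did not pass the bound on each. InhA at 24 h also ran with InhA at 10 h (r = 0.45, 698 of 777 shared calls the same way). This goes against an exchange on the InhA slide if InhA acts alike at these times. Yet KAR1 at 10 h ran against InhA at 24 h (r = -0.169), although it ran with InhA at 10 h (r = 0.43). Arrays 1 and 2 of the KAR1 slide carry KAR1 in Cy3 and arrays 3 and 4 in Cy5, while in the other groups the orientation alternates.

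The mixture correlated more with InhA than with KAR1 at 2 h (r = 0.64 and 0.23), but with median centring the order turned (0.24 and 0.648). Shared water RNA or array positions may contribute. Between arrays of different number and position r had a mean of 0.444, between the bounds of 0.35 and 0.5 set beforehand. Each side of such a split held fewer arrays, which lowers r by noise alone, and the covariance was 0.00875 against 0.00987. The lower r thus does not show such a contribution. If all arrays of that time carry the same water RNA, the split does not separate it. Shared water RNA therefore cannot be told apart from a shared response. The mixture correlated with InhA at 10 h, on another slide, more than KAR1 at 2 h did, by 0.186 in r, which is consistent with an InhA response in the mixture.

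Arrays of opposite dye correlated at r = -0.47 to 0.09 at 2 h, below 0 in each pair of the KAR1 and InhA groups and above 0 in 2 of the 4 pairs of the mixture. The test of wrong dye labels went against them, but only weakly. With 1 orientation turned, KAR1 at 2 h correlated with KAR1 at 10 h less strongly than as labelled, by -0.064 in absolute r (0.046 against 0.11). Over the 4 pairs of opposite-dye arrays, which reuse the same 4 arrays, it was -0.062 to -0.049. InhA with InhA at 10 h (0.14 labelled, -0.004 turned) and the mixture with InhA (0.176 and 0.029) and KAR1 (0.075 and -0.066) at 10 h went the same way. Across compounds the turned value was larger in size, at KAR1 with InhA at 10 h (-0.01 and 0.047) and InhA with KAR1 at 10 h (0.008 and -0.083). The test takes the response at 2 h to resemble that at 10 h, and with correlations this small it cannot exclude wrong labels. Whether a probe-specific dye effect is the source stays open, since the Cy5 over Cy3 component of the KAR1 arrays at 2 h correlated at 0.212 with that at 10 h, between the bounds of 0.1 and 0.3. The component correlated at 0.68 to 0.80 among the 2 h groups and at 0.32 to 0.41 between these and KAR1 at 24 h, but at -0.191 between InhA at 2 and 10 h and -0.053 between the mixture and InhA at 10 h. As the mean ratio of both orientations, it also holds any difference between the RNA on them. It therefore cannot tell such a difference from a dye effect.

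In 63 sets of 4 arrays, 4 held a value far from the other 3, and chance flags about 1 in 20. Probe 145507 had a log2 ratio of -3.37 in KAR1 at 2 h replicate 4, against -2.62 to -2.54 in the others. Probe 147348 had 1.24 in InhA at 10 h replicate 3, against 1.47 to 1.51. Median Cy5 intensity was 75 in KAR1 at 24 h replicate 2, against 58 to 60. In the mixture at 2 h, replicate 1 had 64.5% of spots above background in the water channel, against 88.6% to 90.4%.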

How the results depend on the processing

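Settings for a dye term per group, median centring and same-dye averaging were chosen after seeing the data, as were all alternatives for correlations except the filter and left-out arrays. Counts of changed probes for the 12 comparisons and contrasts gave 114 values under alternatives other than left-out arrays, of which 59 lay within 1.5 times the main count. Of these, 12 came from Aquantile, which leaves log ratios as they are and so tests nothing, and 12 from leaving out the filter, which had removed few probes. Aquantile aside, InhA at 24 h and KAR1 minus InhA at 24 h stayed within that range in 8 settings each, KAR1 at 24 h in 6, InhA at 10 h in 5, KAR1 at 10 h and KAR1 minus InhA at 10 h in 4, and the 2 h results in 1 to 3. The 48 values of named probes kept their direction under every alternative (728 values), and 83 of these no longer passed the threshold, 22 with median centring and 21 with same-dye arrays averaged. For most of these values the kept direction says little. The rule for naming probes already asked for the same sign on all 4 arrays or, for a contrast, for separated groups. Aquantile, no filter, the compared arrays alone, the replicate block, a dye term for each group and same-dye averaging left the log ratios nearly as they were. No slide block, gene list test or Agilent log ratio at 2 h could be run. Signal over background was lowest in the 24 h InhA group, with 36% to 53.9% of spots above it. The cause was not tested for any change below, except that averaging leaves 14 values in place of 28 and so fewer degrees of freedom.

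Without background correction the counts were 451 for KAR1 at 2 h, 1114 for InhA at 2 h, 1733 for the mixture, 222 for KAR1 minus InhA at 2 h, 415 for the mixture minus KAR1 and 37 for the mixture minus InhA. Agilent's log ratio gave 6401 for KAR1, 2234 for InhA and 2235 for their difference at 10 h. The authors' values gave 860 for InhA at 2 h, 9674 for KAR1 at 24 h and 222 for KAR1 minus InhA at 2 h. The compared arrays alone, without dye term, gave 15 (KAR1 at 2 h), 17 (InhA at 2 h), 1 (mixture), 6 (KAR1 minus InhA at 2 h), 24 (mixture minus KAR1), 3 (mixture minus InhA), 6655 (KAR1 at 10 h) and 2821 (KAR1 minus InhA at 10 h). A dye term for each group gave 3027, 5376 and 1786 for KAR1, InhA and the mixture at 2 h, 3334, 1354 and 133 for KAR1 minus InhA, the mixture minus KAR1 and the mixture minus InhA, and 6582, 2525 and 2752 for KAR1, InhA and their difference at 10 h. Median centring gave 22, 67 and 15 at 2 h with 0, 1 and 0 for the differences, 6091, 54 and 1 at 10 h, and 1225, 4178 and 4742 at 24 h, in the same order. Averaging same-dye arrays gave 12, 78 and 15 at 2 h with 2, 2 and 0 for the differences, 970, 104 and 43 at 10 h, and 3260 for KAR1 at 24 h.

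Whether replicate numbers pair the arrays stays unsettled. Deviations of same-numbered arrays from the mean of their group and dye correlated at -0.06 to 0.47, but those of the 2 same-dye arrays of a group mirror each other, so at 2 and 10 h these values are not independent and number cannot be told from dye orientation. With the replicate block the counts were 2682 for InhA at 2 h, 783 for the mixture, 684 for KAR1 minus InhA at 2 h and 299 for the mixture minus KAR1. The other 8 counts stayed within 1.5 times.

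Leaving out each array in turn gave 542 to 745 (KAR1 at 2 h), 2383 to 3473 (10 h), 5157 to 5328 (24 h), 528 to 4352 (InhA at 2 h), 488 to 647 (10 h), 9133 to 10389 (24 h), 160 to 1121 (mixture), 93 to 1991, 540 to 929 and 10086 to 10924 (KAR1 minus InhA at 2, 10 and 24 h), 77 to 440 (mixture minus KAR1) and 5 to 21 (mixture minus InhA). For the mixture minus KAR1 the count was 111 without KAR1 replicate 1, and 440, 98 and 77 without mixture replicates 2, 3 and 4. For the mixture minus InhA it was 5, 21 and 5 without InhA replicates 1, 2 and 3, and 5 and 6 without mixture replicates 1 and 4. Correlations ranged from 0.137 to 0.387, 0.39 to 0.423 and -0.545 to -0.537 for KAR1 with InhA at 2, 10 and 24 h, 0.141 to 0.279 for the mixture with KAR1 and 0.513 to 0.696 with InhA. Median centring moved them to 0.066, 0.87, -0.527, 0.648 and 0.24, and the authors' values moved those at 10 and 24 h to 0.366 and -0.467.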

Other observations

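Levels in water-imbibed achenes differed between 10 h and 24 h on the slides of both compounds, in part in the same probes. In the water channels of the KAR1 slides 816 probes were at least 2-fold higher and 468 at least 2-fold lower at 24 h than at 10 h, and in those of the InhA slides 1892 and 1519. Of these, 560 were higher and 193 lower on both sets of slides, and 21 moved in opposite directions. The changes correlated at r = 0.54 across probes. These are differences of means of 4 arrays with no test, since among these groups each time and compound was on a slide apart from the others. Water channels of the 2 compounds' slides differed from each other by an SD of 0.60 on the log2 scale at 24 h and 0.08 at 10 h.

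The hypothesis that the compounds shift achenes along this time course was tested, as set down beforehand, against the 10 h to 24 h change in water on the other compound's slides. InhA fold changes at 24 h ran against that change (r = -0.54, from -0.57 to -0.44 over the 4 arrays) and KAR1 fold changes ran with it (r = 0.217, from 0.17 to 0.24). Such signs would be seen if InhA held achenes back and KAR1 moved them forward, a hypothesis that takes the labels of both slides as given. The KAR1 value lay just above the bound set beforehand, and single arrays fell below it. Harvests also differed: at 24 h RNA of germinated and non-germinated achenes was combined in equal amounts, which was not done at 10 h. The change in water may hold that difference, so the hypothesis stays open. The 10 h fold changes showed little of it (r = -0.048 for InhA and 0.068 for KAR1). Times were on separate slides, so differences between slides stay open.

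The file headers of the 24 h InhA arrays carry the slide number that the mixture's arrays carry. Deviations between repeat spots correlated between these groups at a mean r of 0.12 for arrays at the same position and 0.09 for others in Cy3, and at -0.04 and -0.02 in Cy5. Between InhA at 2 h and the mixture the values were 0.49 and 0.45 in Cy3 and 0.48 and 0.34 in Cy5. The gap by position was thus alike in Cy3 but not in Cy5, and the overall level differed. Between KAR1 at 24 h and the mixture they were 0.33 and 0.31 in Cy3 and 0.16 and 0.08 in Cy5. The values of InhA at 24 h with the mixture were lower than all of these, so they do not show a shared slide.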
